A study of Homo sapiens with 6 samples.

How the data were processed

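Total RNA from THP-1 and U937 cells was made into libraries with an Illumina TruSeq RNA kit, per the labels' protocols. FastQC, cutadapt, STAR, HTSeq and the hg38 genome build are named in the submitters' processing notes, without their settings. The name of the deposited table calls its values RPKM in one part and FPKM in another, which are reads or fragments scaled to gene length and sequencing depth. The gene annotation and the software versions are not given in the sources used here.

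Samples were assigned to groups by cell line and dose from their titles. Each column name of the table was then searched for in the text labels and characteristic values of every sample, ignoring case, spaces and punctuation. Labels stored as lists, such as the names of the processing tools, were not searched. All 6 value columns matched no sample and were left out of every step. Only the header line and the number of rows of the table were used.

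Before the data were examined, a comparison of fold changes within each line and a linear model across both lines with cell line as a block had been specified, together with alternative pseudocounts, filters and scalings. None of these was run, because the columns could not be assigned to samples.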

Results

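RNA sequencing was carried out on 2 human monocytic cell lines, THP-1 and U937, each labelled with the p53 mutant R282W. Because all 6 samples share this label, the design holds no group without it. The p53 protein is a transcription factor that responds to DNA damage, and R282W is a substitution in its DNA-binding domain. Both lines were treated for 48 h with DAC or with DMSO, the solvent control. DAC is the usual abbreviation of decitabine, a deoxycytidine analogue that is incorporated into DNA and traps DNA methyltransferases. The doses of DAC were 1 µM and 5 µM. The 6 libraries form 6 groups with 1 library in each, so that each line contributed 3 libraries.

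The design implies a comparison of each dose of DAC with DMSO within each line, a comparison of the 5 µM with the 1 µM dose, and a comparison of the response between the lines. The purpose stated for the series was to measure transcriptional activity after DAC. With 1 library per group, none of the comparisons within a line has a replicate, and neither has the comparison of the response between the lines.

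No expression value is reported for any of these comparisons. The expression table has 26485 rows below its header and 6 value columns, which are numbered and carry no cell line, treatment or dose. None of the 6 column names occurs in the searched labels of any sample. The searched labels and the header line therefore did not assign the columns to THP-1 or U937, or to DMSO or either dose of DAC. Whether another source gives a key was not established. Without one, assignment would require assuming an order or reading the groups from the values themselves. Neither was done. Whether DAC changed the expression of any gene in either line was not analysed here, and the depth of each library is unknown.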

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

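No paired analysis was possible because no column of the expression table names a sample. For the same reason none of the alternatives planned before the data were examined (pseudocount, filter on low values, scaling, model and gene list settings) was run, and the dependence of any expression result on the processing was not examined. The only result recomputed was the assignment of columns, under rules chosen after the column names were seen. Searching the name as exact text left the same 6 columns unmatched, but this stricter search could not have done otherwise. None of the 6 matched exactly 1 sample when the column number alone was searched as a separate number in the titles. The numbers 1 and 5 each occur in the titles of 2 samples, as the DAC dose in either line, and the others in none.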
